A study of Candida albicans with 6 samples.

How the data were processed

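RNA from 6 samples of *Candida albicans* strain SC5314, a standard laboratory strain of this yeast, was measured by RNA sequencing on an Illumina NovaSeq instrument. Per the labels, yeast-form cells at 5000000 cells per ml in RPMI1640 medium were given 32 µg/ml of SP1, a compound known here only by that code, or the same volume of its solvent DMSO, for 3 h at 30 °C. Each group held 3 samples, and RNA was extracted with a RiboPure-Yeast kit. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

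The submitters' processing notes name CASAVA 2.19 and HISAT2 2.0.5. The counting tool, the gene annotation, the genome build and the use of strand were not given in the sources used here. The deposited values were 1 number per gene and sample for 6393 rows, and no column was left unused. Their unit was read from the values as FPKM (fragments scaled by gene length and by library size), deposited after a between-library scaling: each of the 6 deposited columns had the same median ratio to the across-library geometric mean, 1.00305, as median-of-ratios scaling gives. The rows carried NCBI gene IDs. Of these, 6263 matched the RefSeq gene table of assembly ASM18296v3, which gave a gene symbol for 2962, and 130 were rows for unannotated transcripts. Since the authors' build was not given, the table was used for names, lengths and the order of neighbouring genes, and no coordinates are printed.

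Multiplied by the RefSeq gene length, the FPKM of 5840 of the 6263 matched genes (93.2%) were whole multiples of 1 step per library. The tolerance was 0.01 plus a part that grew with the number of reads, so the check is weak for genes with the most reads. For 538 rows the length was inferred from the values, 15 gave none and 54 were at 0 in each library. The multiples were taken as recovered reads. They summed to 17309259, 20368896 and 19062565 in control replicates 1, 2 and 3, and to 16209305, 16571227 and 15052668 in SP1 replicates 1, 2 and 3. The recovered reads were used for depth, shares of reads, the 95% counting intervals of ratios with 1 to 3 reads in a group, which cover counting error only, and some alternatives. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom of 8.31 to 82.7 within groups), so none was taken as a library deposited a second time. This does not show that they came from separate cultures.

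The design fixed before the data were examined assumed read counts and a count model. Because the unit was FPKM, the test was instead limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with a fitted mean-variance trend, and Benjamini-Hochberg adjustment at 0.05. Genes with at least 1 FPKM in at least 3 libraries were tested, which left 6244. Fold changes are on the log2(FPKM + 1) scale, with SP1 over control, and understate the change of genes with low values. Adjusted p-values are limma's unless the set test is named. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

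A total of 34 gene lists was fixed before the data were examined, and 814 of the 893 genes written in them matched a row. Lists with at least 5 tested genes entered limma's camera test, which compares the genes of a list with the other genes, with a preset inter-gene correlation of 0.01. The camera test with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. Counts of genes within a list are given over all genes tested. Counts adjusted over the list alone were the same in 33 of the 34 lists, and in the amino acid biosynthesis list 27 genes fell adjusted over the list alone against 26.

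The genes named in the text follow a rule fixed before the data were examined. The first part took the 8 largest rises and 8 largest falls among genes past the threshold with a symbol, non-overlapping groups and a mean of at least 10 in the higher group, which was set for CPM and was applied to FPKM. The second part took the 3 largest changes in each of the 8 lists with the smallest set-test p and the largest change in each other list. The third part took 14 genes chosen in advance: ERG11, UPC2, CDR1, CDR2, MDR1, GSC1, ECE1, HWP1, ALS3, NRG1, CAT1, HSP90, AOX2 and ICL1. Together these were 65 genes. Genes outside the rule that are named as the few members of a list moving one way were chosen after their values were seen. Some such genes are not reported here.

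The fit was tested on simulated reads drawn for the 6244 genes of this comparison with a dispersion of 0.02, in 5 runs with 200 seeded genes each. It recovered 42.0% of genes changed 1.5-fold, 97.6% of those raised 2-fold, 100% of those raised 4-fold and 93.5% of those lowered to 0.5 of their level, with a mean of 10.8 false calls per run (6.11% of calls). In the data 5347 genes passed the threshold, far more than the 200 seeded. The runs therefore do not cover false calls that arise from composition or scaling. The dispersion was the same for each gene and both groups and was not fitted to the data. Within groups, chi-square per degree of freedom was 8.31 to 18.3 for the control and 24.5 to 82.7 for SP1. The recovery thus holds for that setting and is not the power of this comparison. The comparison of rows with and without a rising neighbour was tested on 153 rows with shuffled fold changes. It passed 0.05 in 6 of 100 runs without an effect and in 100 of 100 runs with a planted one. The planted runs had a median difference of 2.00, larger than in the data (medians of 2.78 and 1.99). Shuffling also removes correlation between rows, so these runs do not show how the comparison performs at the difference seen.

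The alternatives changed 1 choice at a time, except that voom changed the input values with the test and the last one named changed the rows with the scaling. Leaving out a library also loosened the filter from 3 to 2 libraries, so that 6254 to 6276 genes were tested. The alternatives were upper quartile factors, library totals alone, no filter, at least 10 CPM of recovered reads in 3 libraries, limma voom on the recovered reads, the replicate number as a block, each library left out in turn, the 20 most abundant rows left out, a loess correction on gene length (span 0.3), and the 2 other set tests. Those chosen after the data were seen were pseudocounts of 0.1 and 5 FPKM, trimmed mean of M-values factors, protein-coding genes only, genes of at least 500 bases, no mean-variance trend, reads thinned to the shallowest library, and the 20 most abundant rows left out with scaling to the remaining totals.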

Results

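The 6 transcriptomes addressed how *C. albicans* SC5314 cells treated with SP1 at 32 µg/ml for 3 h differed from cells given DMSO, with 3 samples in each group. Recovered reads ranged from 17309259 to 20368896 per library in the control and from 15052668 to 16571227 with SP1. The first principal component held 97.2% of the variance and separated the groups, and the second held 1.28%. Across genes, log2 values correlated with Pearson r of 0.988 to 0.996 within groups and of 0.676 to 0.707 between them, where genes are not independent replicates. The SP1 libraries also differed in composition. The 20 most abundant rows, picked in each library separately, took 36.3% ± 2.50 of reads with SP1 and 14.3% ± 0.598 in the control. Ribosomal RNA rows took 6.03% ± 2.03 and 1.29% ± 0.407 (SD, n = 3 each). These shares can overlap, since rRNA rows were not left out of the 20. The rRNA share was 8.37% in SP1 replicate 3 and 4.98% and 4.74% in the other SP1 libraries.

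SP1-treated cells had higher transcript levels of chaperones and proteasome subunits, and lower levels of genes of glucose uptake, glycolysis, the TCA cycle, copper and zinc homeostasis and the hyphal program. The lists behind these groups passed the camera test with a preset correlation, and none of them passed with an estimated correlation (adjusted p = 0.149 to 0.830). The mitochondrial chaperone gene *HSP78* rose from 43.5 ± 2.32 to 4466 ± 623 FPKM, and the zinc transporter gene *ZRT2* went from 1307 ± 49.9 to 7.90 ± 0.869 FPKM (SD, n = 3). Of 6244 genes tested, 5347 passed an adjusted p of 0.05, of which 2714 rose and 2633 fell. A change of at least 2-fold was found for 3413 genes, 1800 higher and 1613 lower, and a change of at least 8-fold for 649, 415 higher and 234 lower. The SP1 and control libraries did not overlap for 5434 genes (87.0%), against 10% by chance with 3 against 3. This split depended on the scaling between libraries. With library totals in place of the deposited scaling the median log2 fold change of all genes moved by -0.66, 1812 genes were higher and 3590 lower, and 1157 and 2571 were so by at least 2-fold.

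Heat shock genes rose together. Of 26 genes of the heat shock and protein folding list, 22 rose and 4 fell, with a median log2 fold change of 2.93 (camera adjusted p = 0.000131, adjusted p = 0.830 with an estimated correlation). The median was 2.22 with library totals, where 18 rose and 4 fell. It was 1.86, with 15 risen and 4 fallen, without the 20 most abundant rows and with scaling to the remaining totals. That setting moved the median of all genes by -0.26, against -0.66 with library totals. It also takes list members out, so its median and counts are not of the same 26 genes. The largest rises were those of *HSP78* (GeneID 3637414), with a log2 fold change of 6.64 ± 0.11 (SE), the Hsp90 co-chaperone gene *STI1* at 6.19 ± 0.11 and the small heat shock protein gene *HSP21* at 6.18 ± 0.09, which reached 34224 ± 609 FPKM against 470.8 ± 28.8 in the control. *HSP90* rose from 450.8 ± 30.1 to 8297 ± 943 FPKM, an 18.4-fold change (adjusted p = 8.83e-10). The 4 that fell, named after their values were seen, were *HSP12*, *HSP31*, *ASR1* and *ASR2*.

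The proteasome list moved in the same direction. Of its 30 genes, 28 rose, 27 of them by at least 2-fold, and 2 fell. The 2, named after their values were seen, were *UBA1* at -1.16 and *PRE1* at -0.23 (adjusted p = 0.0451). With upper quartile factors 28 rose and 1 fell. The median log2 fold change was 1.94 (camera adjusted p = 6.42e-07, adjusted p = 0.149 with an estimated correlation), or 1.23 with library totals. The core particle subunit genes *PRE9* and *PRE8* had log2 fold changes of 5.50 ± 0.10 and 4.85 ± 0.11. *PRE9* went from 103 ± 3.60 to 4732 ± 468 FPKM, and *PUP2*, another core subunit gene, from 117 ± 7.55 to 2668 ± 310 FPKM. The polyubiquitin gene *UBI4* of this list shares its ubiquitin sequence with *UBI3* of the ribosomal protein list, so the reads of this pair are uncertain.

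Glucose uptake and breakdown genes fell. In the glycolysis and fermentation list 18 of 19 genes fell, 17 of them by at least 2-fold, and the exception was *PDC2*, named after its value was seen. The median log2 fold change was -3.56 (camera adjusted p = 7.18e-06, adjusted p = 0.830 with an estimated correlation). Hexokinase *HXK2* fell by 4.85 ± 0.12 on the log2 scale, pyruvate decarboxylase *PDC11* fell by 4.76 ± 0.13 and glucose-6-phosphate isomerase *PGI1* fell by 4.74 ± 0.15. *PDC11* had 1770 ± 158 FPKM in the control and 64.9 ± 11.8 with SP1. Of 22 hexose transport genes, 18 fell, 3 did not pass the test and *HGT9* rose, again named after its value was seen, with a median of -2.10 (camera adjusted p = 0.000137, adjusted p = 0.652 with an estimated correlation). *HGT6* (GeneID 3638873) had 1054 ± 64.7 FPKM in the control and 16.5 ± 2.44 with SP1, a log2 fold change of -5.92 ± 0.12. *HGT19* (GeneID 3640558) and *HGT12* had log2 fold changes of -5.84 ± 0.13 and -4.55 ± 0.23. The *HGT* genes are a family of related sequences, and values of single members are uncertain where reads could be split between them.

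**Figure D1:**
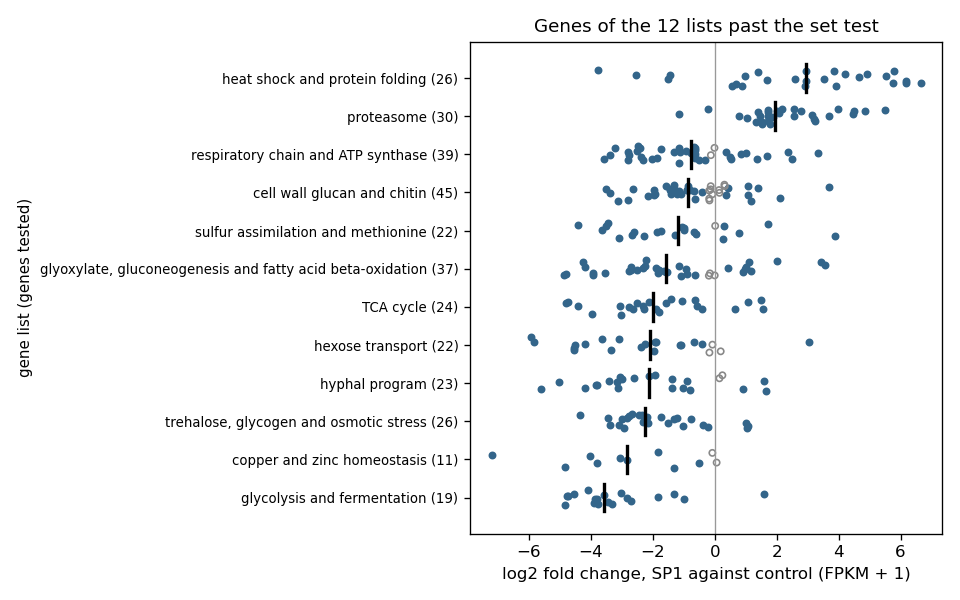
Log2 fold change (SP1 against control, log2 of FPKM + 1) on the x axis for the genes of the 12 lists past the camera test with a preset correlation, with the number of genes tested in brackets on the y axis. Filled points are genes with an adjusted p under 0.05, open points are other genes and black bars are list medians, which lie at 2.93 for heat shock and 1.94 for proteasome genes and between -0.76 and -3.56 for the other 10 lists.

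Mitochondrial and alternative carbon pathways were lower as well. Of 24 genes in the TCA cycle list, which also holds NADP-dependent isocitrate dehydrogenases, 20 fell. Among them were the NADP-dependent *IDP2*, aconitase *ACO1* and citrate synthase *CIT1*, with log2 fold changes of -4.81 ± 0.13, -4.74 ± 0.13 and -4.41 ± 0.13. *LPD1*, *LSC2* and *PYC2*, named after their values were seen, were among the 4 that rose. The list median was -2.01 (camera adjusted p = 0.000725, adjusted p = 0.830 with an estimated correlation). In the list for the glyoxylate cycle, gluconeogenesis and fatty acid beta-oxidation, 25 of 37 genes fell and 9 rose, with a median of -1.56 (camera adjusted p = 0.00583, adjusted p = 0.830 with an estimated correlation). Its largest change was in the dicarboxylate transporter gene *JEN2* at -4.85 ± 0.13, and isocitrate lyase *ICL1* was at -2.77 ± 0.28. Of 39 respiratory chain and ATP synthase genes, 27 fell and 10 rose, with a median of -0.76 (camera adjusted p = 0.0140, adjusted p = 0.830 with an estimated correlation, and camera adjusted p = 0.0530 with a minimum of 10 CPM). Relative to all genes its median was -0.79 (quartiles -2.39 and 0.14), -0.62 with that minimum (-2.22 and 0.31) and -1.75 after the length correction (-2.29 and -0.38). The largest change in it was that of *AOX2*, an alternative oxidase outside the cytochrome pathway, from 2807 ± 165 to 235.6 ± 13.1 FPKM.

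Most genes of the lists for storage carbohydrate, for copper and zinc and for sulfur fell. In the trehalose, glycogen and osmotic stress list 23 of 26 genes fell, with a median log2 fold change of -2.25 (camera adjusted p = 6.40e-05, adjusted p = 0.652 with an estimated correlation). Its largest changes were in *GCY1* at -4.36 ± 0.13, glycerol-3-phosphate dehydrogenase *GPD2* at -3.45 ± 0.17 and phosphoglucomutase *PGM2* at -3.39 ± 0.10. The 3 that rose, named after their values were seen, were the osmotic signalling genes *HOG1* at 1.02, *PBS2* at 1.04 and *SKO1* at 1.08. Of 11 copper and zinc genes, 9 fell and 2 did not pass the test, with a median of -2.82 (camera adjusted p = 0.00285, adjusted p = 0.398 with an estimated correlation). These included *ZRT2* (GeneID 3635861) at -7.20 ± 0.10, the secreted zinc-binding protein gene *PRA1* at -4.85 ± 0.25 and the zinc-responsive regulator gene *CSR1* at -4.04 ± 0.11. In the sulfur assimilation and methionine list 16 of 22 genes fell and 5 rose, with a median of -1.17 (camera adjusted p = 0.0103, adjusted p = 0.830 with an estimated correlation). *MET15* fell by 4.40 ± 0.18 on the log2 scale. The 5 that rose, named after their values were seen, were *MXR1* at 3.89, *CBF1* at 1.72, *SUL2* at 0.79, *SAM2* at 0.30 and *MET6* at 0.28 (adjusted p = 0.0488). With library totals 2 genes of the sulfur list rose and 19 fell.

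Genes of the hyphal program were lower with SP1. Of 23 genes 18 fell and 3 rose, *HWP2*, *SAP4* and *SAP6*, named after their values were seen, with a list median of -2.12 (camera adjusted p = 0.000934, adjusted p = 0.830 with an estimated correlation). *ECE1*, which encodes the precursor of the toxin candidalysin, went from 1844 ± 113 to 57.1 ± 13.8 FPKM, and its log2 fold change was -5.01 ± 0.15. The adhesin genes *HWP1*, *ALS3* and *HYR1* had log2 fold changes of -3.84 ± 0.16, -3.40 ± 0.14 and -4.19 ± 0.17, and *IHD1* (GeneID 3640291) had one of -5.60 ± 0.13. *NRG1*, a repressor of filamentation, also fell, from 628.8 ± 21.5 to 34.0 ± 2.69 FPKM. Of the 45 cell wall glucan and chitin genes, 27 fell and 8 rose, with a median of -0.86 (camera adjusted p = 0.0132, adjusted p = 0.830 with an estimated correlation). That call was lost after a loess correction on gene length (camera adjusted p = 0.0742) and without genes under 500 bases (camera adjusted p = 0.0592). Relative to all genes the list median was -0.89 (quartiles -1.46 and 0.11), -0.77 with the correction (-1.47 and 0.30) and -0.71 without the short genes (-1.34 and 0.23). The glucan synthase gene *GSC1* had a log2 fold change of -0.68 ± 0.12 (adjusted p = 0.000475), which became -0.18 ± 0.11 with that correction (adjusted p = 0.158) and -1.39 with library totals (adjusted p = 5.20e-07). The largest change in the list went the other way, the cell wall protein gene *PIR1* at 3.70 ± 0.17.

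**Figure D2:**
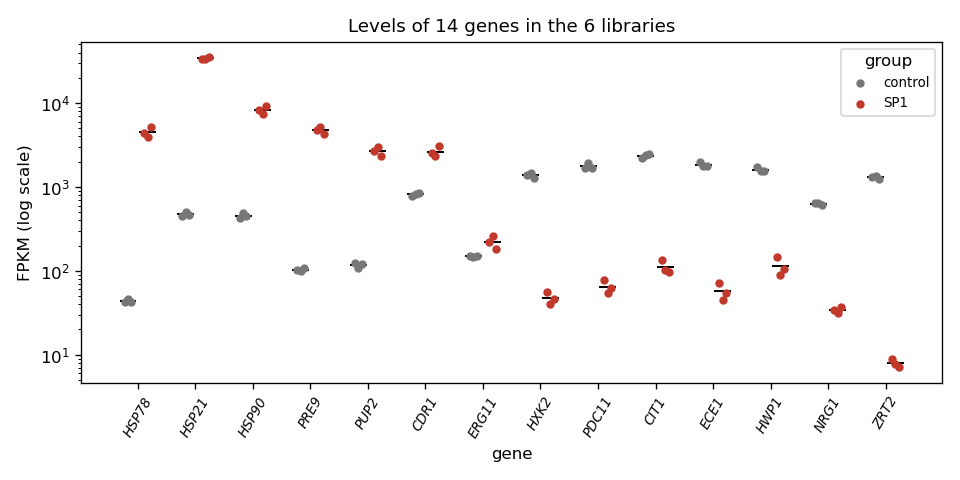
FPKM on a log scale (y axis) of 14 genes (x axis) in each of the 3 control (grey) and 3 SP1 (red) libraries, with the group mean as a black bar. *HSP21* lay near 34224 FPKM with SP1 against 470.8 in the control, *ZRT2* near 7.90 against 1307, and *ERG11* at 220 against 148.

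Genes tied to azole drugs moved in different directions. *ERG11*, which encodes the target of azole antifungals, had 148 ± 2.95 FPKM in the control and 220 ± 38.0 with SP1, a log2 fold change of 0.56 ± 0.13 (adjusted p = 0.00216), but of -0.16 with library totals (adjusted p = 0.406). *UPC2*, a regulator of ergosterol genes, rose by 1.38 ± 0.10 on the log2 scale and was at 0.70 with library totals. The efflux pump genes *CDR1* and *CDR2* rose by 1.68 ± 0.11 and 2.48 ± 0.11, and *CDR1* was at 0.96 with library totals. *MDR1*, another efflux pump gene, did not pass the test at -0.56 ± 0.29 (adjusted p = 0.0967). Its SP1 values were 41.3, 40.5 and 97.9 FPKM, and without SP1 replicate 3 its log2 fold change was -0.98 (adjusted p = 1.68e-05). It was -1.27 with library totals (adjusted p = 0.000887) and -0.58 with voom (adjusted p = 0.0350). With the replicate number as a block it was -0.56 (adjusted p = 0.0188). Without SP1 replicate 1 or 2 it was -0.36 and -0.35. In the list of drug efflux genes and azole resistance regulators 9 of 21 genes rose and 8 fell (camera adjusted p = 0.872), with *TPO3* (GeneID 3634790), a polyamine transporter gene, at -5.43 ± 0.13. In the ergosterol list 16 of 23 genes fell and 5 rose, *ERG11*, *ERG3*, *ERG4*, *ERG9* and *ERG13*, of which the other 4 were named after their values were seen. The list median was -0.53 and did not pass the set test (camera adjusted p = 0.0950), though it did with library totals (camera adjusted p = 0.0312), where 0 genes rose and 20 fell. Without the 20 most abundant rows and with scaling to the remaining totals 1 rose and 16 fell. *ERG26* had the largest change in it, -2.26 ± 0.14.

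Among genes with a symbol, non-overlapping groups and a mean of at least 10 FPKM with SP1, the 8 largest rises were, apart from *HSP78*, of genes outside the lists past the set test. *RPS27A* (GeneID 30514993), a small ribosomal subunit protein gene, went from 126 ± 15.5 to 42973 ± 4484 FPKM, a log2 fold change of 8.41 ± 0.12. Of the 75 cytosolic ribosomal protein genes 27 rose and 36 fell (camera adjusted p = 0.724), or 16 and 54 with library totals. Relative to all genes the median of that list was -0.23, and -0.74 with the length correction, where it passed as lower (camera adjusted p = 0.0144). *RBR2* (GeneID 3640983) rose by 7.92 ± 0.14 on the log2 scale, the inositol-1-phosphate synthase gene *INO1* (GeneID 3638966) by 6.84 ± 0.14 and the glutamate dehydrogenase gene *GDH3* (GeneID 3648086) by 6.53 ± 0.20. Also among these 8 were 3 tRNA genes, in libraries whose rRNA share of reads was higher too. The control libraries together held 2 reads of *tP(UGG)4* (GeneID 30515413) and 1 read of *tH(GUG)1* (GeneID 30515401). Their ratios of scaled reads were 4999 (95% counting interval 1383 to 41290.5) and 662 (118 to 26209). *tN(GUU)4* (GeneID 30515455) rose from 3.36 ± 1.97 to 476 ± 113 FPKM. tRNA genes have near-identical copies, so these values are uncertain. Among the 8 largest falls chosen in the same way were also the pirin-like gene *PRN1* (GeneID 3639882) at -6.14 ± 0.11, the flavodoxin-like protein gene *PST2* (GeneID 3643909) at -5.65 ± 0.15 and the G1 cyclin gene *CLN3* (GeneID 3642624) at -5.57 ± 0.14.

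The remaining lists did not pass the set test and had members that moved both ways. In the ribosome biogenesis list 36 of 69 genes rose and 21 fell (camera adjusted p = 0.215), or 20 and 32 with library totals, with *NIP7* at 5.18 ± 0.10. For DNA replication and the cell cycle 29 of 51 genes fell and 12 rose (camera adjusted p = 0.101). Without genes under 500 bases this list passed as lower (camera adjusted p = 0.0310), with a median relative to all genes of -0.83 against -0.75. Of 39 oxidative stress and thiol defence genes 14 rose and 19 fell (camera adjusted p = 0.282), and the catalase gene *CAT1* had a log2 fold change of -0.74 ± 0.15 (adjusted p = 0.00100), or -1.45 with library totals (adjusted p = 3.90e-06). Of 25 adhesin genes 14 fell and 7 rose (camera adjusted p = 0.179), and of 37 nitrogen and amino acid uptake genes 20 fell and 13 rose (camera adjusted p = 0.396). Of 30 iron and heme uptake genes 16 rose and 9 fell (camera adjusted p = 0.544), with the ferric reductase-like gene *FRE30* at -5.42 ± 0.19. The yeast-form list had 6 of 13 genes that fell and 4 that rose (camera adjusted p = 0.593), the latter *PIR1*, *RHD1*, *RHD3* and *WH11*. The opaque-cell markers had 7 of 12 that fell and 5 that rose (camera adjusted p = 0.942). The risers were *WOR1*, the regulator of the white-opaque switch, at 4.14 ± 0.15, *SAP3* at 3.77 ± 0.09, *SAP1*, *OP4* and *MFA1*, of which the last 3 were named after their values were seen. *WOR1* had 0.159 ± 0.120 FPKM in the control and 19.5 ± 3.12 with SP1, so its log2 fold change moved with the pseudocount, from 6.32 at 0.1 to 2.24 at 5, and was 7.05 with voom.

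In the endoplasmic reticulum folding list 5 of 13 genes rose, *PDI1* at 2.30 ± 0.11, *LHS1*, *ERO1*, *HAC1* and *KAR2*, and 5 fell, *SEC61*, *ROT2*, *OST1*, *CWH41* and *IRE1* (camera adjusted p = 0.872). All but *PDI1* were named after their values were seen. Protein disulfide isomerase is the product of *PDI1*. The rise and fall counts were 25 and 26 of 57 for amino acid biosynthesis, with *TRP2* at 2.90 ± 0.11 (camera adjusted p = 0.773), and 14 and 11 of 30 for the DNA damage response, with *RAD32* at -3.61 ± 0.09 (camera adjusted p = 0.773). They were 9 and 6 of 16 for phospholipid synthesis, which holds *INO1* (camera adjusted p = 0.724), and 9 and 6 of 20 for sphingolipid and fatty acid synthesis, with *FAD3* at -3.35 ± 0.12 (camera adjusted p = 0.773). For protein mannosylation they were 15 and 16 of 34, with *BMT8* at -3.62 ± 0.18 (camera adjusted p = 0.872), and for secreted proteases, lipases and phospholipases 12 and 10 of 28 (camera adjusted p = 0.872). In mitochondrial ribosomal proteins 8 of 18 genes rose and 7 fell, with *IMG2* at 3.08 ± 0.13 (camera adjusted p = 0.942). In cell integrity signalling 5 of 17 rose, *CNB1* at 2.39 ± 0.13, *MKC1*, *HST7*, *DFI1* and *CMP1*, and 7 fell (camera adjusted p = 0.722). In phosphate starvation 6 of 16 rose and 5 fell, *PHO113* at -2.35 ± 0.19, *VTC3*, *GIT3*, *PHO81* and *PHO15* (camera adjusted p = 0.872). In autophagy 3 of 6 rose, *VPS15*, *ATG9* and *ATG15*, and 2 fell, *VPS34* at -1.55 ± 0.12 and *VAC8* (camera adjusted p = 0.872). With a pseudocount of 5 *VPS34* was at -0.91 and *PHO113* at -1.39. With library totals 12 genes rose and 34 fell in amino acid biosynthesis, 9 and 19 in protein mannosylation, 2 and 14 in cell integrity signalling, 9 and 25 in oxidative stress and thiol defence, and 8 and 24 in nitrogen and amino acid uptake. They were 4 and 8 for the endoplasmic reticulum, 4 and 17 for adhesins, 8 and 38 for DNA replication and the cell cycle, 11 and 15 for iron and heme uptake, 2 and 9 for the yeast-form list and 4 and 7 for opaque-cell markers. For the DNA damage response they were 9 and 16, for phospholipid synthesis 5 and 8, for sphingolipid and fatty acid synthesis 5 and 12, for secreted proteases 10 and 15, for mitochondrial ribosomal proteins 5 and 10, for phosphate starvation 4 and 9, for autophagy 1 and 3 and for drug efflux 6 and 13. The members listed here without a value were named after their values were seen. Median, mean and test differed in sign for 4 lists. The median and mean were -0.20 and 0.17 for cytosolic ribosomal proteins (test lower), 0.09 and -0.72 for drug efflux (test lower), -0.09 and 0.26 for the endoplasmic reticulum (test higher), and -0.46 and 0.44 for opaque-cell markers (test lower).

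The camera test with a preset correlation passed 12 of the 34 lists, 2 higher and 10 lower with SP1. With an estimated correlation, where the test has 4 residual degrees of freedom, camera passed 0 lists, and 2 had an unadjusted p under 0.05. With library totals the medians were -1.57 for cell wall genes, -1.47 for the respiratory chain and -1.86 for sulfur. With fry 30 lists passed, and 34 passed its test for change in either direction. Library totals turned the median of 10 lists from above to below 0, none of them among those 12: ribosome biogenesis (0.54 to -0.15), iron and heme uptake, phospholipid synthesis, autophagy, DNA damage response, mitochondrial ribosomal proteins, phosphate starvation, sphingolipid and fatty acid synthesis, drug efflux, and secreted proteases.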

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

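Among the alternatives, pseudocounts of 0.1 and 5, trimmed mean of M-values factors, protein-coding genes only, genes of at least 500 bases, no mean-variance trend, thinned reads and scaling to the totals without the 20 most abundant rows were chosen after the data were seen. The count of genes past the threshold stayed between 4617 and 5402 in the alternatives run, that of genes changed at least 2-fold between 2779 and 3728, that of higher genes between 1812 and 2756 and that of lower genes between 2424 and 3590. The lowest and highest counts with 1 library left out were 5105 and 5372, 3397 and 3456, 2593 and 2709, and 2512 and 2663, with 12 lists past the set test each time. Of the 3413 genes changed at least 2-fold, 2770 were so in the same direction with library totals. The number of lists past the set test was 0 with an estimated correlation and 30 with fry. These tests differ in construction, since camera compares a list with other genes and fry does not. *ERG11* reversed with library totals, to -0.16, where each fold change moves by the factor between library totals and the deposited scaling. Over the other named genes and alternatives, 1405 values stayed on their side of the threshold with the same direction, 5 gained significance, each of *MDR1*, and 2 lost it, *GSC1* with the length correction and *ERG11* at 0.28 without the 20 most abundant rows and scaled to the remaining totals. Of the list results with the preset correlation, 741 stayed, 4 gained and 3 lost significance, while with an estimated correlation the 12 calls were lost. With the length correction or without genes under 500 bases, the cytosolic ribosomal proteins passed as lower (camera adjusted p = 0.0144 and 0.0337), and the cause was not tested.

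The groups share the replicate numbers 1 to 3. With the number as a block 5294 genes passed, of which 3414 changed at least 2-fold, and *MDR1* passed at -0.56 (adjusted p = 0.0188, against 1.68e-05 to 0.328 over its alternatives). Deviations of libraries with the same number correlated at 0.07, -0.14 and -0.03, so the numbers were not taken as pairing, and not each library correlated best with its own number. No count model was fitted, as the deposited unit is FPKM, although recovered reads entered some alternatives such as voom. Corrections on GC content, alone or with the block, were not run, since no gene sequences were used. Median-of-ratios scaling is that of the deposited values. Depth limited genes with few reads, such as the tRNA genes with 1 or 2 control reads.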

Other observations

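RNA classes outside the protein-coding genes were higher with SP1. Of 87 tRNA rows 70 rose and 5 fell, with a median log2 fold change of 2.31, and of 73 snoRNA rows 52 rose and 10 fell, with a median of 2.04. The 4 rRNA rows and the 5 snRNA rows rose, and of 105 rows for unannotated transcripts 80 rose and 20 fell, with a median of 1.80. With library totals the medians stayed above 0, at 2.00 for tRNA, 1.41 for snoRNA and 1.36 for the unannotated rows, and with voom the tRNA median was 3.49. snoRNA rows took 2.34% ± 0.248 of the reads with SP1 and 0.164% ± 0.00378 in the control (SD, n = 3), while tRNA rows took 0.0234% ± 0.00359 and 0.00662% ± 0.000371. A large part of the tRNA share with SP1 came from 1 row of uncertain value, *tP(UGG)4*. It held 5168 reads over the SP1 libraries and 2 over the control libraries. Among 21 gene families grouped by symbol after the data were seen, outside the fixed lists, 0 passed limma's camera test and 4 had an unadjusted p under 0.05. These 4 were ADE, the purine synthesis genes, with 7 of 9 fallen (adjusted p = 0.163), VMA, the vacuolar ATPase genes, with 7 of 9 fallen (adjusted p = 0.258), the telomere-associated TLO genes with 8 of 11 risen (adjusted p = 0.258), and the zinc cluster factors ZCF with 20 of 34 fallen (adjusted p = 0.258). TLO genes are near-identical copies, so their values are uncertain. The direction of these medians held with library totals.

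Of the tests that follow, those on the rRNA share, on length within genes of at least 1000 bases and on the 4 classes of non-coding RNA were chosen after the values were seen. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. In limma, the real split was 1 of 10 with as many genes past the threshold (5347, highest other 0), changed at least 2-fold (3413, highest other 0), higher (2714, highest other 0) and lower (2633, highest other 0). At an unadjusted p under 0.05 the other splits gave 0 to 9 genes. For the set test 5 of the 10 splits, the real one included, passed as many lists, with 12 for the real split and 14 for the highest other. Each other split sets 2 libraries of 1 group and 1 of the other against the rest, which leaves part of the difference between the groups in it.

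The first pattern is the size of the change, with 3413 of 6244 genes at least 2-fold apart. Without the 20 most abundant rows and with scaling to the remaining totals, 3519 genes changed at least 2-fold. Thinning each library to the shallowest left 3412. The deposited scaling already removes a factor shared by the genes of a library, such as depth or reads lost to abundant genes. Neither check could therefore lower the count much, and neither decides whether abundant genes or depth contribute. The rRNA share of reads was 4.69 times as high with SP1, and a difference in RNA quality or library preparation cannot be told apart from the treatment, because it runs along the groups. A response of the cells to SP1 stays open beside it, as untested.

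The second pattern is that shorter genes were higher with SP1. Protein-coding genes under 500 bases had a median log2 fold change of 0.62 and those of 2000 bases or more of -0.18. Membership of short genes in the fixed lists does not account for it, as the difference in median between genes under 500 bases and longer ones was 0.81 (95% bootstrap interval 0.56 to 1.03) outside the lists. Reads from changed neighbouring genes stay open, since the difference was 0.35 (0.09 to 0.86) among genes whose neighbours both changed less than 2-fold. A length bias may contribute and stays open too, with a Spearman rho of -0.035 (-0.071 to -0.0015) across genes of at least 1000 bases, which are not independent replicates.

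The third pattern is the rise of tRNA and snoRNA rows. The 82 rows with no protein-coding neighbour up by 2-fold still had a median log2 fold change of 1.99 (95% bootstrap interval 1.31 to 2.32). Reads from such neighbours therefore do not account for the rise as a whole. Unannotated and non-coding rows were not counted as neighbours, so reads from those rows stay open. The 71 rows with a protein-coding neighbour up by 2-fold had a median of 2.78, higher by a permutation test (2-sided p = 0.00176). Reads from these protein-coding neighbours may therefore add to the rise. Rows can share neighbours, and tRNA genes have near-identical copies. The rows are therefore not independent replicates, and the p and the interval do not measure spread between samples. More unadenylated or short RNA in the SP1 libraries cannot be told apart from a response to SP1, since the lowest median of the rRNA, snRNA, snoRNA and tRNA rows was 2.04 and the classes rose along the groups.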
